A study of Mus musculus with 6 samples.

How the data were processed

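RNA was sequenced from sorted mouse macrophages of 2 groups of 3 libraries each, all from animals on a high-fat diet for 4 months, with libraries made from TRIzol-extracted RNA by a kit for stranded mRNA, per the labels' protocols. Per the labels, the WT libraries came from mice with loxP-flanked Alkbh5 and no Apoe, and the CKO libraries from mice that also carried Cre recombinase in the Lyz2 locus, which acts in myeloid cells. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the 3 libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

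The authors deposited 1 table per library with FPKM values, per the file headers, that is reads scaled by the listed gene length and by the total of reads assigned to the listed genes. The submitters' processing notes list, with no role or order, fastp 0.19.3, HISAT2 2.1.0, StringTie 1.3.4d, Cufflinks, featureCounts 1.6.2, DESeq2 1.22.1 and GATK 4.0.11.0, with genome build mm10. Each table held 21936 genes with the same annotation, and all values were finite and at least 0. Of the gene identifiers, 21894 were in GENCODE M21 for the same genome, 21681 of them with the same chromosome, start and end, and 21857 were protein coding there. Multiplying FPKM by gene length gave whole multiples of 1 step in every library, for 100% of values within 0.01 reads, so reads per gene could be recovered. The recovered totals served for depth, for noise between libraries and for 1 alternative test.

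The recovered totals were 18418903, 17944578 and 16660206 reads for the libraries labelled WT and 17133311, 15422154 and 17802617 for those labelled CKO. In these libraries 3 reads of a gene 1 kb long correspond to 0.163 to 0.195 FPKM. For a gene without reads in a group the floor was 3 reads at its own length, 0.302 FPKM for Retnlg. Intervals and floors of this kind cover counting error only, since the reads carried no molecular identifiers. Counting noise was compared with the spread between libraries by a chi-square statistic per degree of freedom over genes with at least 20 reads in a pair of libraries. It was 2.16 to 3.18 within groups and 404 to 449 between groups, so no pair of libraries agreed within counting noise.

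Genes with FPKM of at least 1 in at least 3 libraries were tested with limma 3.58.1 (lmFit, eBayes with an intensity trend) in R 4.3.3 on log2(FPKM + 1), with the group as the only term. Fold changes are on that scale, labelled CKO minus labelled WT, and understate changes of low genes. P-values were adjusted by the Benjamini-Hochberg method and called under 0.05. Gene lists were tested with camera from limma at a preset correlation of 0.01 between genes, adjusted over the lists with at least 4 tested genes, and again with an estimated correlation and with fry. With 3 libraries per group that correlation is estimated imprecisely. A call lost in that setting therefore neither refutes a list nor upholds it. For single genes an exact two-sided permutation test of 3 against 3 libraries cannot give a p under 0.1. Neighbouring genes were compared with a two-sided Fisher's exact test. Tables and exact tests were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

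The tests, the 53 gene lists and the rule for naming genes were fixed before the data were examined. Named were Alkbh5, Lyz2, Apoe and Ccl5, then in each direction the 10 genes with the largest change among called genes with a mean FPKM of at least 1 in the higher group, no overlap between groups and no clone-style symbol. From each gene list described, up to 4 tested members with the smallest p were added, with members needed for sentences on cell types; some results are not reported here. Which of the lists that were not called are described was decided after their values were seen. Alternatives were the replicate number as a block, each library left out, pseudocounts of 0.1 and 0.5, no filter, a mean FPKM of at least 5, median-of-ratios scaling, quantile normalization, limma without trend or with array weights, and other thresholds. The filter was applied again to the remaining libraries when 1 was left out, which removes genes expressed in only 1 group, so these fits were also run with the tested genes held. Those fits, the limma voom test on the recovered reads, and the secretory phenotype list without chemokine and NF-kB members, were chosen after seeing the data.

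The limma and camera steps were tested on simulated reads for the same genes and library sizes, with 9769 genes passing the filter. Of planted changes of 1.1-fold 32.0% were called, of 1.25-fold 89.3%, of 1.5-fold 99.0% and of 2-fold 99.5%. Of all calls 4.68% were unchanged genes, and 0 of 20 unchanged lists were called. Genes were simulated independently and with 1 noise level beyond counting for all. False list calls from correlated genes, or errors from genes that vary more, could therefore not appear. Of the simulated genes tested 8956 were unchanged, unlike the data, where most genes were called.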

Results

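The series asked how macrophages of Apoe-deficient mice on a high-fat diet differ when the RNA demethylase gene Alkbh5 is deleted in myeloid cells, with macrophage senescence and the chemokine Ccl5 named in its title. ALKBH5 removes methyl groups from N6-methyladenosine, a common mark of mRNA. Expression was measured by RNA sequencing in 3 libraries labelled WT and 3 libraries labelled CKO, with 15422154 to 18418903 reads per library assigned to genes. Values are deposited FPKM, given as mean ± SD over n = 3 libraries.

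Alkbh5, the deleted gene, was higher in the libraries labelled CKO, against the label. Its FPKM was 3.77, 3.95 and 3.88 in the libraries labelled WT and 9.15, 8.61 and 8.50 in those labelled CKO, a log2 fold change of 1.00 (SE 0.050, limma adjusted p = 4.78e-09). These values count reads over the whole gene (chromosome 11, 60536381 to 60558512, mm10), and cannot show whether an exon was missing from the transcript. Lyz2, which encodes lysozyme and whose locus carries the Cre, fell from 15116 ± 992 to 6556 ± 211 FPKM (chromosome 10, 117277331 to 117282321, limma adjusted p = 2.51e-10). Its near-identical neighbour Lyz1, with which reads could be split, read 4.01 ± 0.645 against 2.02 ± 0.644 FPKM. Apoe, which carries cholesterol in lipoproteins and is labelled as null in both groups, read 1635 ± 29.3 FPKM in the libraries labelled WT and 89.6, 97.3 and 98.1 in the 3 labelled CKO (chromosome 7, 19696109 to 19699188, limma adjusted p = 4.23e-15). Here too the values cannot show whether the transcript was intact. Alkbh5 thus went against the label. Apoe, labelled null in both groups, was abundant in the libraries labelled WT and differed between the groups by -4.09 on the log2 scale. The labels do not account for that difference, and its cause was not tested. For both reasons, every direction that follows refers to the libraries as labelled, not to a checked genotype.

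**Figure D1:**
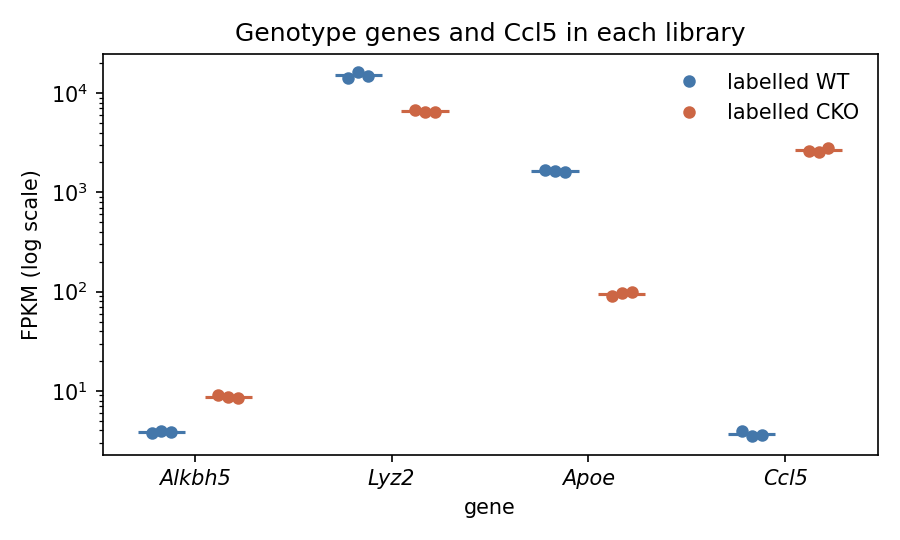
FPKM of Alkbh5, Lyz2, Apoe and Ccl5 on a log axis, 1 point per library with a line at the group mean, for the 3 libraries labelled WT and the 3 labelled CKO. Alkbh5 averaged 3.87 FPKM in the libraries labelled WT and 8.75 in those labelled CKO, and Ccl5 3.65 and 2656.

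Ccl5, a chemokine that attracts T cells and monocytes, rose from 3.65 ± 0.222 FPKM in the libraries labelled WT to 2656 ± 124 in those labelled CKO. Its log2 fold change was 9.16 (SE 0.043, limma adjusted p = 4.02e-17; chromosome 11, 83525778 to 83530518). It was higher in all 3 libraries labelled CKO, and the exact permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow.

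Inflammatory effectors were among the genes with the largest increases in the libraries labelled CKO. The granule proteins Ngp and Ltf had the largest decreases on log2(FPKM + 1). As a ratio of means Pcp4l1 fell further, 462-fold against 402-fold for Ltf and 353-fold for Ngp, each under 1 FPKM in the libraries labelled CKO. Nos2, the inducible nitric oxide synthase, went from 0.158 ± 0.0210 to 1258 ± 18.5 FPKM, and Saa3, an acute-phase protein of macrophages, from 5.49 ± 0.197 to 4861 ± 122. Il1b, the interleukin-1 beta cytokine, rose by 8.25 on the log2 scale, Ccl2 and Ccl7, chemokines for monocytes, by 7.70 and 7.49, and Acod1, which makes itaconate, by 7.30. Slfn4, an interferon-responsive gene, and the formyl peptide receptors Fpr1 and Fpr2 rose by 6.82, 6.64 and 6.35. In the other direction Ngp and Ltf went from 108 ± 19.3 to 0.305 ± 0.0861 and from 42.0 ± 7.77 to 0.104 ± 0.0330 FPKM. Hpgd, which breaks down prostaglandins, changed by -4.86, Atp6v0d2, a subunit of the lysosomal proton pump, by -4.44, and Gas6, a bridge between dying cells and their phagocytic receptors, by -4.26. The remaining genes with the largest decreases were Pcp4l1 (-4.80), Mamdc2 (-4.41), Arhgap19 (-4.39), the costimulatory receptor Cd28 (-4.28) and Apoe (-4.09), which is labelled null in both groups.

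Of 9953 genes tested, 8069 changed at a limma adjusted p under 0.05, 3038 higher and 5031 lower in the libraries labelled CKO. The higher genes made up 37.7% of these calls, and 51.2% after median-of-ratios scaling. That scaling moved the fold changes by a median of 0.16 and called 4058 genes higher and 3874 lower. Of the calls 831 rose and 998 fell by at least 1 on the log2 scale. The values of the 2 groups did not overlap for 82.5% of genes, where chance gives 10%. Beyond counting noise the libraries of a group varied by 1.95% (labelled WT) and 2.09% (labelled CKO), over genes with at least 1000 reads. So small a spread lets small changes be called, and it may be technical.

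**Figure D2:**
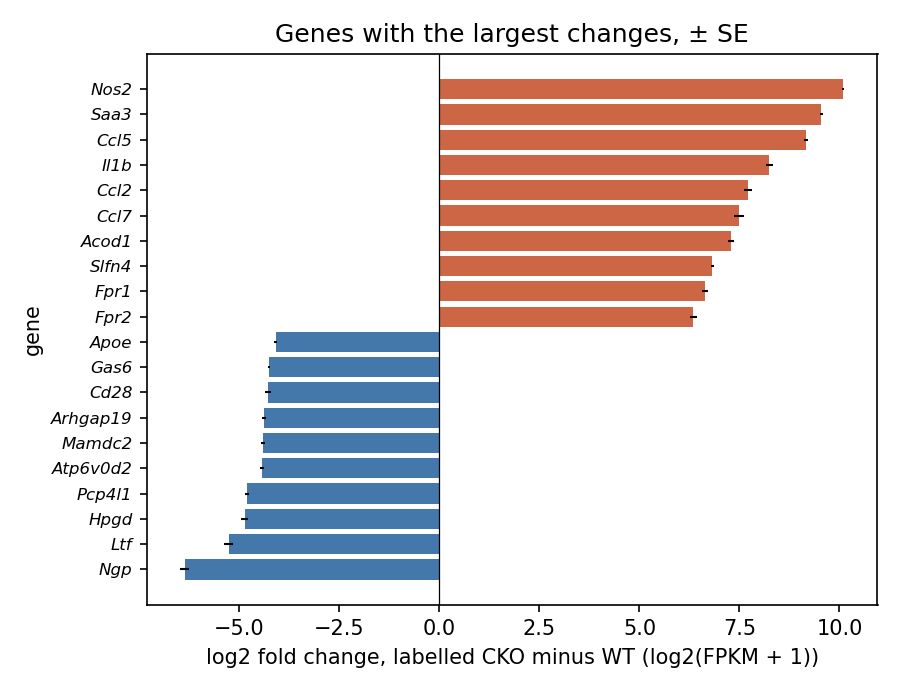
Log2 fold changes with SE of the 10 genes with the largest increases and the 10 with the largest decreases, libraries labelled CKO minus libraries labelled WT on log2(FPKM + 1). Bars run from -6.37 for Ngp to 10.09 for Nos2.

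Interferon and inflammatory genes rose as groups. All 27 tested type I interferon-stimulated genes were higher, as were all 21 tested inflammatory cytokines and NF-kB targets, with the same counts adjusted over the list alone (camera adjusted p = 4.00e-18 and 4.58e-14). These calls did not hold with an estimated correlation, at adjusted p = 0.219 and 0.0929. Irf7, a transcription factor for interferon genes, went from 11.6 ± 0.423 to 530.2 ± 7.68 FPKM, the antiviral enzyme Rsad2 rose by 5.28 and the ubiquitin-like Isg15 by 5.84. Among NF-kB targets Ptgs2, which makes prostaglandins, rose by 6.23 and Socs3, a brake on cytokine signalling, by 5.67. Of 21 interferon-gamma targets 19 rose and 2 fell, adjusted over the list alone too (camera adjusted p = 1.08e-10, adjusted p = 0.306 with an estimated correlation). The guanylate-binding Gbp5 rose by 4.88, the peptide transporter Tap1 by 2.80 and Cd274, the ligand of an inhibitory T cell receptor, by 2.90. All 16 MHC class I genes rose, adjusted over the list alone as well, with H2-Q4 at 2.81 and H2-T22 at 2.74 (camera adjusted p = 1.49e-09, adjusted p = 0.258 with an estimated correlation). Of these 1 fell after quantile normalization, and the class I genes share sequence, so their reads may be split uncertainly. Of 10 CC chemokines 8 rose and 2 fell, with Ccl6 at -1.90, and of 7 CXC chemokines 6 rose, with Cxcl3 at 5.91, Cxcl2 at 5.30 and Cxcl10 at 4.93. Counts were the same adjusted over the list alone, and the camera adjusted p was 5.31e-04 and 3.43e-05, or adjusted p = 0.306 and 0.122 with an estimated correlation. Some of these lists share members, so their calls are not independent. Tap1 is in the interferon-gamma and MHC class I lists, Cxcl10 in the interferon-gamma and CXC lists, and Cxcl2 in the NF-kB and CXC lists.

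Genes of glycolysis and of the oxidant response rose beside them. Of 25 glycolysis and hypoxia genes 24 rose and 1 fell, adjusted over the list alone as well (camera adjusted p = 1.47e-14, adjusted p = 0.0929 with an estimated correlation). Ldha, which makes lactate, went from 153 ± 2.48 to 892 ± 12.6 FPKM, the glycolytic enzyme Eno1 from 105 ± 0.834 to 600.4 ± 4.37, and Pfkfb3, which sets the rate of glycolysis, rose by 3.55. Of 23 antioxidant and NRF2 targets 19 rose and 2 fell, adjusted over the list alone as well (camera adjusted p = 4.56e-08, adjusted p = 0.241 with an estimated correlation). Hmox1, which degrades haem, went from 198 ± 5.19 to 4646 ± 131 FPKM, and the mitochondrial superoxide dismutase Sod2 rose by 3.95.

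Senescence genes went both ways. Of 18 senescence regulators 5 rose and 12 fell, adjusted over the list alone too, and the list was not called (camera adjusted p = 0.734). After median-of-ratios scaling 6 rose and 8 fell, and after quantile normalization 5 rose and 9 fell. The list was fixed without a direction for each gene, so these counts and this test cannot speak for or against senescence. Cdkn1a, the cell cycle inhibitor p21, went from 12.8 ± 0.586 to 188 ± 1.11 FPKM, while its relative Cdkn1c went from 56.6 ± 3.42 to 3.52 ± 0.187. Glb1, the enzyme behind senescence-associated beta-galactosidase staining, changed by -0.86 and the deacetylase Sirt6 by 1.03. Cdkn2a, named after its values were seen, was below the filter, with 3 reads over the libraries labelled WT and 18 over those labelled CKO. Cdkn2b, also named after its values were seen, went from 0.204 ± 0.108 to 2.25 ± 0.0969 FPKM. Lmnb1, named in the same way, went from 3.83 ± 0.691 to 1.33 ± 0.220 FPKM. Of 17 p53 targets 7 rose and 5 fell, adjusted over the list alone too (camera adjusted p = 0.303, median -0.02 but mean 0.28), with Mdm2 at 2.18, Fas at 2.61 and Sesn1 at -3.30. Of 32 genes of the senescence-associated secretory phenotype 23 rose and 8 fell, adjusted over the list alone as well (camera adjusted p = 3.11e-06, adjusted p = 0.130 with an estimated correlation), with Il1a at 5.79 and Tnfrsf1b at 1.97. Without the members it shares with the chemokine and NF-kB lists, 11 of 20 rose and 8 fell, and camera gave an unadjusted p = 0.0502, or p = 0.0995 with an estimated correlation. This subset was chosen after the data were seen. Cell cycle genes were lower in 29 of 31 cases, adjusted over the list alone too (camera adjusted p = 2.69e-05, adjusted p = 0.102 with an estimated correlation), with the microtubule regulator Stmn1 at -2.99 and the mitotic genes Ccnb1 and Top2a at -1.77 and -1.62. Of 34 cell cycle genes 5 reached 10 FPKM in either group: Top2a read 4.22 ± 0.251 FPKM in the libraries labelled WT, and the call was lost among genes with a mean FPKM of at least 5 (adjusted p = 0.153).

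Most lipid and lysosomal genes fell. Of 22 lipid uptake and foam cell genes 19 fell and 3 rose, adjusted over the list alone as well (camera adjusted p = 4.09e-04, adjusted p = 0.122 with an estimated correlation). Trem2, a lipid receptor, went from 164 ± 3.92 to 15.4 ± 0.316 FPKM and Pparg, a lipid-sensing nuclear receptor, from 22.4 ± 0.247 to 0.647 ± 0.0293, whereas the scavenger receptor Msr1 rose from 14.6 ± 0.832 to 155 ± 1.43. Of 22 cholesterol biosynthesis genes 18 fell and none rose, adjusted over the list alone too, and 1 rose after either rescaling (camera adjusted p = 4.07e-04, adjusted p = 0.331 with an estimated correlation). Insig1, a sterol sensor, changed by -1.83 and the enzyme Cyp51 by -1.46. Of 30 lysosome and autophagy genes 25 fell and 5 rose, adjusted over the list alone too, with the mannosidase Man2b1 at -1.83, but the protease Ctsc at 2.37 and the autophagy adaptor Sqstm1 at 1.38 (camera adjusted p = 0.00460, adjusted p = 0.306 with an estimated correlation). All 40 cytosolic ribosomal protein genes fell, also adjusted over the list alone and after both rescalings, with Rpl3 at -2.33 (camera adjusted p = 3.21e-11, adjusted p = 0.325 with an estimated correlation). All 11 mitochondrially encoded mRNAs fell, adjusted over the list alone too, and 8 after median-of-ratios scaling, with mt-Nd1 at -0.87 (camera adjusted p = 0.0185, adjusted p = 0.419 with an estimated correlation).

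**Figure D3:**
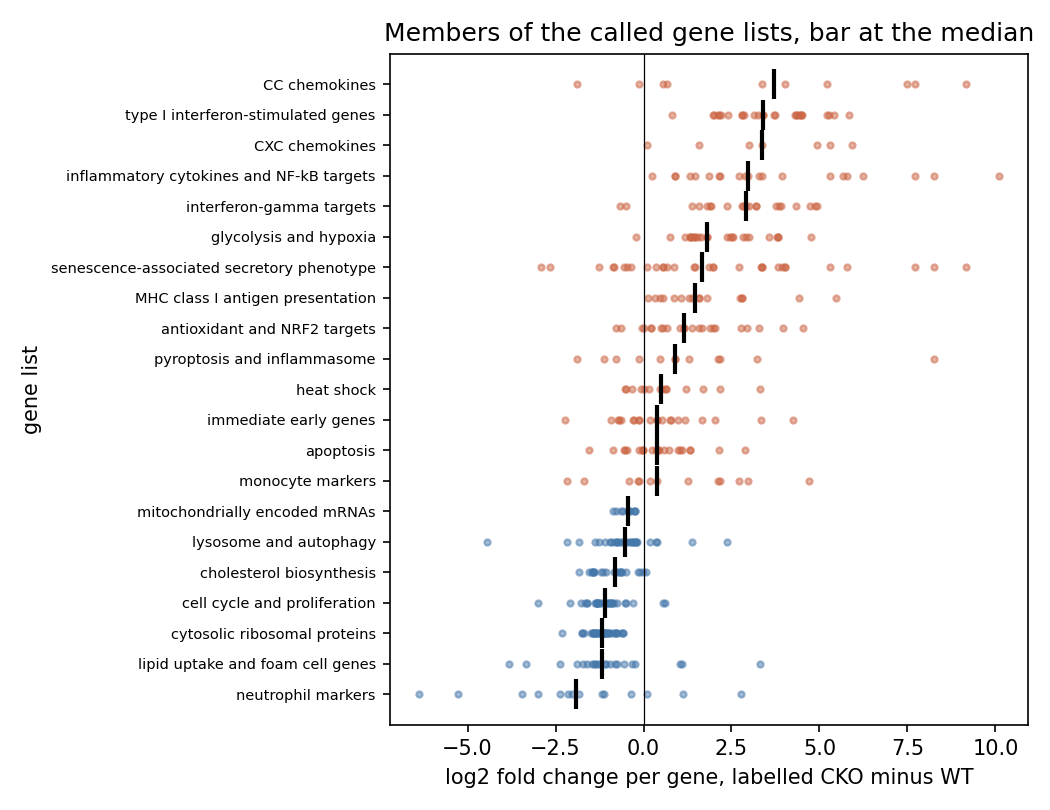
Log2 fold change of each tested member of the 21 called gene lists, libraries labelled CKO minus libraries labelled WT, 1 point per gene and a bar at the list median. Medians run from -1.93 for neutrophil markers to 3.70 for CC chemokines.

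Smaller calls were made for apoptosis, pyroptosis, heat shock, immediate early and monocyte genes. Of 23 apoptosis genes 14 rose and 5 fell, with the inhibitors Birc3 and Bcl2a1a at 2.16 and 2.87, and of 12 pyroptosis genes 8 rose and 4 fell, with Nlrp3 at 2.18 (camera adjusted p = 0.0101 and 0.0167, adjusted p = 0.260 and 0.366 with an estimated correlation). Of 14 heat shock genes 9 rose and 4 fell, with Hspa1b at 3.30, and of 21 immediate early genes 12 rose and 8 fell, with Ier3 at 4.23 (camera adjusted p = 0.0167 and 0.0434, adjusted p = 0.306 and 0.325 with an estimated correlation). Of 13 monocyte markers 8 rose and 4 fell, with Hp at 4.69 and Ccr2, the receptor that brings monocytes into tissue, at -2.17 (camera adjusted p = 0.0429, adjusted p = 0.419 with an estimated correlation). Adjusted over the list alone the counts of these 5 lists were the same. The pyroptosis call was lost after median-of-ratios scaling (adjusted p = 0.0568), and the monocyte and immediate early calls after either rescaling. With the same genes tested and 1 library left out, only the monocyte call among these 5 was lost, without CKO replicate 3 (adjusted p = 0.0539). With the filter applied again the heat shock, immediate early and monocyte calls were lost without any 1 library labelled CKO, but members expressed in that group alone then left the test. Among genes with a mean FPKM of at least 5 these 3 calls were lost (adjusted p = 0.146, 0.0701 and 0.0833), and the monocyte call also with no filter (0.0931).

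Markers of other cell types went both ways, and lists with fewer than 4 tested members were not tested as lists. Of 14 neutrophil markers 11 fell and 2 rose, adjusted over the list alone too (camera adjusted p = 0.0491, adjusted p = 0.662 with an estimated correlation), and the call was lost with limma voom (0.129) and among genes with a mean FPKM of at least 5 (0.210). With the same genes tested it was also lost without WT replicate 2, CKO replicate 1 or CKO replicate 3 (adjusted p = 0.0544, 0.0562 and 0.0575), and held without each of the others. With the filter applied again it was lost without any 1 library labelled CKO, where no member left the test (adjusted p = 0.0599 to 0.0786), and without any 1 labelled WT, where members expressed in that group alone did. S100a9 went from 425 ± 85.0 to 37.3 ± 5.10 FPKM and Elane, neutrophil elastase, from 7.19 ± 0.436 to 0.0190 ± 0.0330, while Lcn2 and Mmp8 went from 21.7 ± 4.54 to 152 ± 7.25 and from 7.07 ± 1.35 to 16.6 ± 1.66. Among macrophage core genes 7 of 18 rose and 10 fell, adjusted over the list alone too, with Adgre1, the F4/80 antigen, at 1.80, Cd14 at 1.87 and the mannose receptor Mrc1 at -3.41 (camera adjusted p = 0.748). Of 6 tested erythroid and platelet markers 5 fell and none rose, adjusted over the list alone too (camera adjusted p = 0.126), with Ppbp at 101 ± 6.71 against 38.5 ± 3.16 FPKM. Pf4, another member, read 68.9 ± 1.61 against 74.0 ± 6.08 FPKM. Of 5 tested mast cell, basophil and eosinophil markers 4 fell, adjusted over the list alone too (camera adjusted p = 0.0921, called after median-of-ratios scaling at 0.0467, and adjusted p = 0.366 with an estimated correlation), with Prg2 at 6.53 ± 0.633 against 1.47 ± 0.128 FPKM. Of 23 T and NK cell markers 3 reached 1 FPKM in either group and these 3 fell, with Il7r at 80.8 ± 2.15 against 48.4 ± 0.779 FPKM. That level was reached by 9 of 17 dendritic cell, 6 of 16 B and plasma cell, 5 of 14 endothelial, 3 of 12 adipocyte, 2 of 12 hepatocyte, 1 of 18 fibroblast and mesothelial and 1 of 12 smooth muscle markers. Of those tested, 4 dendritic cell markers rose and 4 fell, and 2 B and plasma cell markers rose and 3 fell. For endothelial markers 2 rose and 2 fell. The 1 fibroblast and mesothelial and 1 smooth muscle marker tested rose, and 2 of 3 adipocyte markers fell. Of 2 tested hepatocyte markers 1 rose and 1 fell, the latter being Trf at 32.0 ± 0.314 against 2.98 ± 0.207 FPKM. Ppbp, Pf4, Prg2, Il7r and Trf were named after their values were seen.

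Changed genes near the targeted loci were counted because such loci can carry flanking chromosome of another strain. Per the labels both groups carried the loxP-flanked Alkbh5, so a flank there would be shared and the count could not show it. With most genes changed elsewhere too, the count near Lyz2 had little room to show an excess. Within 5 Mb of Alkbh5 61 of 75 tested genes changed, against 81.1% elsewhere (odds ratio 1.02, 95% interval 0.561 to 1.97, two-sided Fisher's exact p = 1), and within 5 Mb of Lyz2 28 of 33 (odds ratio 1.31, interval 0.498 to 4.35, exact p = 0.823). Correlations of log2 values over tested genes were 0.997 to 0.998 within groups and 0.826 to 0.831 between groups, and the first principal component held 98.1% of the variance and separated the groups.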

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

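The voom results and the fits that hold the tested genes were chosen after the data were seen. With 1 library left out the genes changed numbered 7331 to 7561, or 7796 to 7874 with the tested genes held. A log2 change of at least 1 left 1829 genes, 831 higher and 998 lower, by its own construction, and a mean FPKM of at least 5, with 6402 genes tested, left 3185 lower. Limma voom called 3035 genes higher and 5049 lower. Camera called 21 of 47 tested lists, and 0 with an estimated correlation (adjusted p of those 21 lists 0.0929 to 0.662); fry, which does not compare a list with other genes, called 42, and all 21 in the same direction. The correlation is estimated imprecisely from 3 libraries per group, and the cause of the lost calls was not tested. Ccl5, Alkbh5, Lyz2 and Apoe kept direction and call in every alternative, with Ccl5 at 9.12 to 9.20 and Alkbh5 at 0.97 to 1.02 without 1 library. Of 146 named genes 120 kept their call in all 6 of these fits, the other 26 being below the filter in some, and all 146 kept it with the tested genes held. Rbm15 lost its call under both other scalings and Rbm15b under median-of-ratios scaling.

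With the replicate number as a replicate block genes changed numbered 8041, 3018 higher and 5023 lower. Deviations of same-numbered libraries correlated at 0.019, 0.012 and -0.039, and not every library correlated best with its own number. These values gave no sign of a pairing. With so few libraries they cannot tell whether same-numbered libraries shared a litter or day, which the labels do not say. Of the 8069 calls 7969 were shared with the block, in the same direction, and no named gene or list changed its call.

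Lists that turned direction without a camera call in either setting did so at these adjusted p-values, and the cause was not tested. Chemokine receptors turned with a pseudocount of 0.1 (0.999), no filter (0.949), a mean FPKM of at least 5 (0.407) and voom (0.975). Oxidative phosphorylation turned with no filter (0.975), a mean FPKM of at least 5 (0.978), quantile normalization (0.593) and fry (0.135). B and plasma cell markers turned with no filter (0.677), median-of-ratios scaling (0.889) and quantile normalization (0.946). Fry turned complement (0.579) and, with a call, endothelial (0.0314) and resident peritoneal macrophage genes (0.0213). Leaving out some libraries turned lists too, with chemokine receptors at 0.349 to 0.375, oxidative phosphorylation at 0.998, dendritic cell at 0.818 to 0.856, B and plasma cell at 0.855 to 0.875 and, with the tested genes held, 0.992, endothelial at 0.969 to 0.979, resident peritoneal at 0.972 to 0.976, alveolar at 0.636 to 0.730 and Kupffer cell genes at 0.858 to 0.924. Over all fits without 1 library, turned or not, the adjusted p of these 8 lists was in the same order 0.349 to 0.994, 0.608 to 0.998, 0.219 to 0.856, 0.855 to 0.992, 0.735 to 0.979, 0.349 to 0.979, 0.220 to 0.730 and 0.342 to 0.924. Near Alkbh5 the odds ratio turned from 1.02 to 0.870 in a window of 2 Mb, with no call in either. Over the 1000 genes of highest variance the median correlation between groups was 0.336, by the choice of those genes. Depth limits genes under the floor of 3 reads.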

Other observations

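All tests of explanations here were chosen after the result was seen, except the count of sample splits. Genes of the RNA methylation machinery went both ways. Of 11 writers of N6-methyladenosine 2 rose and 3 fell, adjusted over the list alone too, and after median-of-ratios scaling 4 rose and 0 fell (camera adjusted p = 0.745, direction higher although the median was -0.04), with Zc3h13 at 0.60. Of 11 erasers and readers 2 rose and 7 fell, adjusted over the list alone too (camera adjusted p = 0.745, median -0.25 but mean 0.0065), and after median-of-ratios scaling 4 rose and 5 fell, with the reader Igf2bp2 at 1.66 and Ythdf3 at -0.72. Genes of alternative activation split, 4 of 13 higher and 9 lower (camera adjusted p = 0.304). With the filter applied again the list was called lower without any 1 library labelled CKO (adjusted p = 0.0434 to 0.0473), but Arg1 and Ccl22 then left the test, and with the tested genes held it was not called (0.288 to 0.329). Arg1, which consumes arginine, went from 0.0517 ± 0.0283 to 35.2 ± 1.64 FPKM, and Clec10a from 8.09 ± 0.146 to 0.468 ± 0.0443. Among cholesterol efflux genes 11 of 17 fell (camera adjusted p = 0.223), with the lysosomal lipase Lipa at -1.94 and Nceh1 at -2.33. Phagocytic receptors split too, 6 of 20 higher and 13 lower (camera adjusted p = 0.303), with Marco at 5.56 and Mfge8, a bridge to dying cells, at -2.52. Oxidative phosphorylation genes were lower in 18 of 30 cases and higher in 10, a split that turned to 5 and 14 after median-of-ratios scaling (camera adjusted p = 0.847, direction higher although the median was -0.12). Adjusted over the list alone the counts of these lists were the same. Of all 9953 tested genes 3038 were called higher and 5031 lower, so a majority of lower members is not by itself particular to a list. Of the Y-linked genes Ddx3y, Kdm5d and Eif2s3y had 0 reads in all 6 libraries, and Uty had 2 reads over the libraries labelled WT and 0 over those labelled CKO.

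With 10 splits of the 6 libraries the share of splits with as many calls cannot fall under 0.1. With limma the labelled split called 8069 genes and was the 1 split with that many, and the highest of the others called 0, with 10 to 21 genes at an unadjusted p under 0.05. Every other split mixed the 2 groups, so the difference between the groups entered its spread and left little room for calls. These splits therefore do not measure a rate of false calls.

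Alkbh5 was higher in the libraries labelled CKO. Reads from exons outside the deletion, with transcription and RNA decay unaltered, would leave its level at or below that of the libraries labelled WT. The log2 fold change of 1.00 (SE 0.050) argues against this as the whole cause, though it is the pattern itself and not a separate test. Scaling is argued against for a change relative to other genes, since the change was at least 1.12 under both other scalings. Both align the groups across genes, so a shift of all RNA in 1 group was not tested. An exchange of the group labels cannot be told apart from the labelled design: Lyz2, lower by a log2 change of -1.20 in the libraries labelled CKO, goes with the labels, but 17 other macrophage genes ranged from -3.41 to 2.99, so the level of Lyz2 may follow macrophage state. A higher level of a truncated transcript, by whatever route, stays open and was not tested.

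Inflammatory genes were higher in the libraries labelled CKO. Scaling is argued against, since after quantile normalization, which does not move all genes alike, all 21 tested members rose and the list median lay 3.08 above that of all genes (camera adjusted p = 4.36e-12, although without this normalization the list was not called with an estimated correlation, adjusted p = 0.0929). A preparation day, pool or stimulus that differed between the groups may have contributed and cannot be told apart from the genotype, because the labels give no batch and the group would follow it. Beyond counting noise the libraries of a group varied by 1.95% and 2.09% (coefficient of variation, genes with at least 1000 reads, from medians over genes), but Ltf varied by 18.5% and Ngp by 17.9% among the libraries labelled WT, so a close agreement did not extend to every abundant gene. The deletion of Alkbh5 stays among the open explanations, as untested.

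Of 14 tested neutrophil markers 11 were higher in the libraries labelled WT, with Retnlg at least 10.7-fold higher against a floor of 3 reads per library and S100a8, the most abundant beside S100a9, at 153 ± 25.9 against 33.4 ± 3.48 FPKM. Cells of the neutrophil lineage are a candidate source, although the cells were sorted as macrophages and 3 of 18 list members are in another list fixed here. The list test did not decide, with an adjusted p of 0.0171 to 0.0575 without 1 library and the same genes tested, and 0.662 with an estimated correlation, and Lcn2 and Mmp8 were higher in the libraries labelled CKO. Within the libraries labelled WT 11 of 14 tested members, Lcn2 and Mmp8 among them, were highest in replicate 2 and lowest in replicate 3, an order seen in 14.5% of all tested genes. A change of these genes within macrophages cannot be told apart from such cells, since either could vary between libraries.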
